A study of Homo sapiens with 9 samples.

How the data were processed

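Platelet RNA of 9 donors was measured by RNA sequencing, with 6 libraries from persons with HIV under antiretroviral treatment and 3 from healthy persons. Per the labels' protocols, platelets were enriched by negative selection with magnetic cell sorting, RNA was extracted with Trizol, and libraries were made with Illumina protocols. The groups hold different donors and the labels give no pairing and no batch, so no paired or blocked fit applied. The p-values measure the spread between donors.

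Per the submitters' processing notes, the authors used HTSeq 0.6.1, DESeq2 (no version given) and genome build hg19. The aligner, the gene annotation, the strand setting and any filter on reads are not given in the sources used here. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart. The annotation used here for names and for gene overlaps is of another build, so no coordinates are given. Gene names are those of the deposited tables, and 28 names that a spreadsheet had turned into dates were looked up by the Ensembl ID of the same row, which resolved 26.

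The authors deposited 2 tables. The larger deposited table holds, per library, a signal in the unit of normalized counts, which is gene counts that the authors divided by a size factor per library, for 23368 named genes. It also holds the authors' mean over the 9 libraries, their log2 fold change with its standard error, their test score (a Wald statistic, per the file headers) and their p-value with its adjusted p-value. A further 1337 rows held no gene name and no values and were left out. The smaller deposited table holds normalized counts, again a signal, of 4722 genes from another quantification, with a lowest gene mean of 42.4, and 4703 of its genes are also in the larger table.

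The design had assumed plain gene counts and an edgeR test. Because the deposited values are normalized, the test laid down for that case, limma on log2(value + 1), took its place, and edgeR became an alternative. Whole reads could be recovered from the larger table: with a tolerance of 0.01, 100% of the values above 0 in each library were whole multiples of the value of 1 read. That value multiplied by the median-of-ratios size factor of the recovered reads was 2 in each of the 9 libraries, so every count that the authors had normalized was an even number. The text uses the recovered reads, which are the deposited counts divided by 2, to state depth and to run the count tests. Depth was 4840789 to 7687306 recovered reads per library. Reads in the smaller table were 2.14 to 2.16 times the recovered reads of the larger table in the median gene. The division by 2 enters this ratio, which therefore overstates the gap between the counts behind the 2 tables. Odd and even numbers were about equally frequent in the smaller table (48.8% to 50.9% odd).

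Y-linked genes, XIST and their neighbours (98 genes) were left out of every test and of the depth totals, because the libraries come from human donors. Genes with a normalized count of at least 10 in at least 3 libraries were tested, which kept 7839. The minimum was set after the unit was known and before any test was run. limma 3.58.1 was run in R 4.3.3 with a variance trend and robust moderation. Fold changes are differences of group means on the log2(value + 1) scale. For genes near 0 in some libraries they can be smaller or larger than the fold between mean counts. The Benjamini-Hochberg adjusted p had to be under 0.05. Adjusted p-values without another tool's name are from this limma fit. Alternatives were edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, limma-voom with quality weights, other scalings (TMM, upper quartile, library totals), other filters, pseudocounts of 0.5 and 8, a leukocyte score, an erythroid score or 1 surrogate variable (sva 3.50.0) as a covariate, the smaller table, and leaving out each library in turn. The edgeR fit with TMM, DESeq2 on doubled reads, limma without robust moderation, TMM in limma and in the list tests, both pseudocounts and the fit without HIV libraries 1 and 5 were chosen after seeing the data. The closing section gives their effect.

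Gene lists were fixed before the data were examined: 35 lists for platelet function, HIV infection and treatment, general cell processes and the other blood cells that a platelet preparation can hold. Of these, 34 had at least 5 tested members. The list of genes on the mitochondrial genome had no tested member and is void, and T cell receptor and immunoglobulin constant genes were not tested. Lists were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 34 lists, beside camera with an estimated correlation and fry. The marker lists were also summarised per library as mean log2 CPM with a prior count of 2 and compared by a two-sided exact permutation test over the 84 splits of 9 libraries into 6 and 3, whose smallest possible p is 0.0119.

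The rule for naming genes was fixed before the data were examined. It names ABCC4, which the series title names; up to 10 genes per direction past the threshold, or, where fewer pass, the genes of smallest p up to 5 per direction, with a mean of at least 5 CPM and every HIV library on the same side of the healthy mean; up to 4 members of smallest p of each list; and the 5 genes with the highest mean CPM. Clone-based identifiers were not named. The minimum of 5 CPM did not apply to list members, and some of those named rest on few reads. Over the 9 libraries together, MX2 had 62 reads, CXCR4 109, APBB1IP 119, ADRA2A 125 and ABCD3 158. Genes that the authors' deposited table calls were named as well, and any other gene was chosen after its values were seen.

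limma, edgeR and camera at the preset correlation were tried on simulated counts with the means, spread and depth of these libraries, with 200 of 7839 genes changed, in 5 simulations of the HIV and healthy comparison. limma recovered 1.60% of genes changed 1.5-fold, 4.00% of those changed 2-fold, 30.4% of those changed 3-fold and 68.4% of those changed 5-fold, and 4.40% of its calls were false. edgeR recovered 1.20%, 4.00%, 30.0% and 70.8%, with 4.68% false. camera found a list raised 1.5-fold in 5 of 5 simulations. Simulated genes vary independently of each other, unlike the real ones.

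Libraries of the same group differed far beyond counting noise: over the 18 pairs the chi-square per degree of freedom ran from 50.8 to 204, and Pearson's r of the log2 values across genes ran from 0.875 to 0.932. No pair was a repeat of the same library. Tables were read with Python 3.11.15 and pandas 2.3.3, and gene detection at equal depth was computed with vegan 2.7.1.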

Results

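Platelets carry RNA inherited from megakaryocytes, and their transcriptome was profiled here by RNA sequencing in 6 persons with HIV under antiretroviral treatment and in 3 healthy persons, with 1 library per donor. The recovered depth was 4982128 to 6259284 reads in the healthy libraries and 4840789 to 7687306 reads in the HIV libraries. The 5 genes with the highest mean CPM are given as means over all 9 libraries. B2M, the light chain of class I antigen-presenting molecules, held 11.7% of reads on average, PPBP, a platelet chemokine precursor, held 5.96%, ACTB, cytoplasmic actin, held 5.30%, SPARC, a matrix glycoprotein stored in platelet granules, held 2.83% and C21orf7 held 2.44%. The 10 highest genes together held 37.3% ± 2.0 of reads in healthy libraries (SD, n = 3) and 37.9% ± 1.26 in HIV libraries (SD, n = 6).

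The comparison of HIV with healthy libraries asked which platelet transcripts differ in abundance, and the series title names ABCC4 as its gene of interest. ABCC4 (ENSG00000125257), a transporter that exports cyclic nucleotides and organic anions and resides in platelet granules and membranes, had 1524 ± 432 normalized counts in healthy libraries (SD, n = 3) and 6427 ± 2312 in HIV libraries (SD, n = 6). The fitted difference was 4.11-fold, with a 95% interval from 2.59-fold to 6.51-fold. All 6 HIV libraries, at 4194 to 9546, lay above all 3 healthy libraries, at 1091 to 1956, and 528 to 5266 reads per library stood behind these values. ABCC4 had the smallest p of all genes tested, yet it did not pass the threshold over 7839 genes.

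The log2 fold change of ABCC4 was 2.04 ± 0.31 (SE) with an adjusted p of 0.0815 in limma. An exact permutation test of ABCC4 alone, two-sided over 84 splits, gave p = 0.0119, the smallest that 6 against 3 libraries allow. Adjusted over the list alone, the limma p of ABCC4 was 1.56e-04 among the 15 tested ABC transporters. It was 2.81e-04 among the 27 tested genes of dense granules and lysosome-related organelles. The series title names ABCC4, and whether it was chosen on these samples is not given in the sources used here, so those values are not taken as independent evidence. On the recovered reads, edgeR gave an adjusted p of 0.209 and DESeq2 gave 3.74e-05, so whether ABCC4 passed depended on the tool. Over the 30 alternatives its log2 fold change ran from 1.82 to 2.24 and its adjusted p from 2.00e-07 to 0.394. The lowest adjusted p came from limma without a filter on low genes, where ABCC4 had the same values and log2 fold change.

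Across the transcriptome, limma found 0 of 7839 genes past the threshold, with 253 genes at an unadjusted p under 0.05, of which 172 were higher and 81 lower in HIV libraries. Chance alone would give 392 such genes. edgeR found 0 of 6450 genes, with 198 at an unadjusted p under 0.05, and DESeq2 found 1, ABCC4, with 310. The groups did not overlap in 150 genes, or 1.91% of those tested, against 2.38% by chance. The median log2 fold change was -0.01 and the median standard error 0.43.

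Besides ABCC4, the genes of smallest p with higher values in all 6 HIV libraries than the healthy mean did not pass the threshold. ST3GAL1, a sialyltransferase, had 427 ± 40.8 normalized counts in healthy and 979 ± 231 in HIV libraries (SD, n = 3 and 6), a log2 fold change of 1.17 ± 0.26 (SE). METTL7A, a methyltransferase, stood at 1.46 ± 0.39, NID1, the basement membrane protein nidogen 1, at 1.69 ± 0.46 and SF1, a splicing factor, at 1.09 ± 0.33. On the lower side, DYNLL1, a dynein light chain, had a log2 fold change of -0.92 ± 0.28, SNHG3, a small nucleolar RNA host gene, of -0.97 ± 0.32 and HSDL1 of -0.86 ± 0.30. SC5DL, a cholesterol synthesis enzyme, stood at -1.47 ± 0.52 and CNTN4, a contactin, at -4.89 ± 1.64. The value of CNTN4 ran from -5.86, without HIV library 4, to -2.50, in edgeR, and HIV library 4, at 259 normalized counts, lay within the healthy range. All 9 of these genes had a limma adjusted p of 0.9997.

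The authors' deposited table lists 4 genes with an adjusted p under 0.05. ABCC4 and METTL7A are higher in HIV libraries in the authors' deposited table, with log2 fold changes of 1.79 and 1.29 and adjusted p-values of 2.43e-07 and 0.0371. CPXM2, a carboxypeptidase-like protein, and NOMO1 are lower in the authors' deposited table, with log2 fold changes of -1.95 and -1.55 and adjusted p-values of 0.0106 and 0.0176. ST3GAL1 has an adjusted p of 0.0941 in the authors' deposited table. In limma and in edgeR, 0 of these 4 genes passed. DESeq2 run again with a prior on fold changes passed 2 of the 4 on doubled reads and 1 on the recovered reads. The healthy libraries spread widely for both lower genes: CPXM2 had 120 ± 114 normalized counts in healthy and 12.8 ± 14.8 in HIV libraries, and NOMO1, which has near-identical copies that could share its reads, had 2916 ± 2693 and 783 ± 558 (SD, n = 3 and 6).

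**Figure D1:**
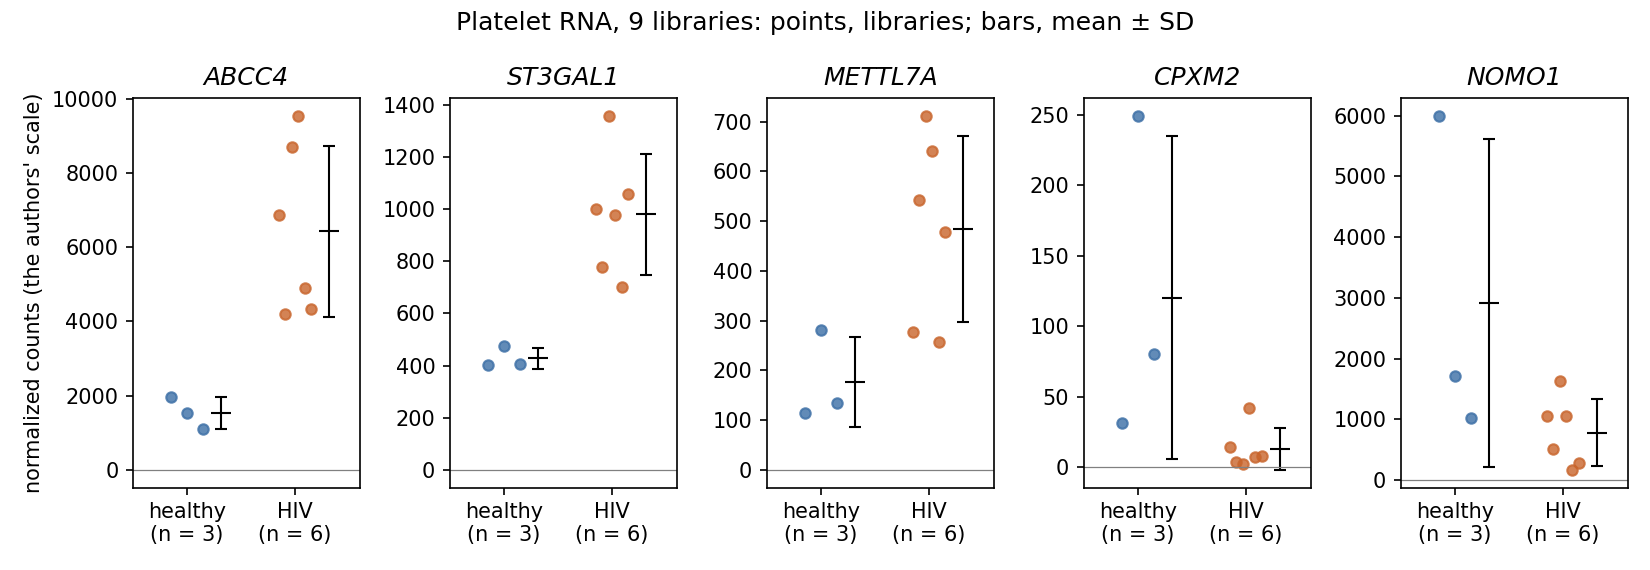
Normalized counts, on a linear axis of its own for each gene, of ABCC4, ST3GAL1, METTL7A, CPXM2 and NOMO1 in 3 healthy and 6 HIV platelet libraries; points are libraries, and bars show the mean ± SD beside them. ABCC4 lies between 4194 and 9546 in HIV libraries and between 1091 and 1956 in healthy libraries, while the healthy libraries spread widely for CPXM2 and NOMO1.

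Platelet gene groups were close to level between HIV and healthy libraries. Among 40 receptors for adhesion and agonists, 26 had higher and 14 lower values in HIV libraries, with a median log2 fold change of 0.11 (camera adjusted p = 0.233). CD36, a receptor for thrombospondin and oxidised lipoproteins, had 4628 ± 4290 normalized counts in healthy and 8006 ± 745 in HIV libraries (SD, n = 3 and 6) and a log2 fold change of 1.18 ± 0.40 (SE), which did not pass; without healthy library 1, CD36 was past the threshold at 1.90 with a limma adjusted p of 0.0253, the lowest over its 29 alternatives, which ran from 0.71 to 1.90. TBXA2R, the thromboxane receptor, stood at 0.42 ± 0.27 and ADRA2A, an adrenergic receptor, at -0.98 ± 0.52. Among 32 alpha granule cargo genes, 18 were higher and 14 lower, with a median of 0.04 (adjusted p = 0.265). PSAP, the saposin precursor, had a log2 fold change of 0.66 ± 0.22 and MMRN1, the factor V carrier multimerin 1, of 0.69 ± 0.29, and neither passed. The 27 genes listed for dense granules and lysosome-related organelles had a median of 0.13 (adjusted p = 0.233). HPS1 stood at 0.56 ± 0.30 and NBEAL2 at 0.54 ± 0.38 beside ABCC4 in that list.

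Signalling genes of platelets went both ways, with 32 of 53 higher, 21 lower and a median of 0.11 (camera adjusted p = 0.233). APBB1IP, the adaptor RIAM, stood at -1.99 ± 0.70, PRKCA, protein kinase C alpha, at -0.66 ± 0.28 and CSK, a Src-inhibiting kinase, at 0.81 ± 0.35. Cytoskeleton and proplatelet genes had a median of 0.12 over 55 members (adjusted p = 0.233), with MYH9, nonmuscle myosin, at 0.37 ± 0.22 and PDLIM1 at -0.43 ± 0.22. Megakaryocyte transcription and differentiation genes had a median of -0.05 over 27 members (adjusted p = 0.842), secretion machinery of -0.04 over 21 (0.895), coagulation factors and regulators of 0.11 over 13 (0.867) and eicosanoid synthesis of 0.06 over 14 (0.856). RUNX1, a megakaryocyte transcription factor, stood at -0.70 ± 0.38. Among the 15 ABC transporters, 8 were higher and 7 lower, with a median of 0.04 (adjusted p = 0.676). fry's test for change in either direction gave an adjusted p of 5.37e-05 for the ABC transporters, and an unadjusted p of 0.0179 for the 14 members without ABCC4. ABCD3, a peroxisomal transporter, had a log2 fold change of -2.81 ± 1.17, which did not pass and ran from -3.41 to -1.72 over the alternatives, with -1.72 in edgeR.

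Antigen presentation and interferon genes had the smallest p-values of the lists in camera at the preset correlation, without passing. Genes of dense granules and lysosome-related organelles had the smallest with an estimated correlation and in fry's directional test. Of 12 class II genes, 10 had lower values in HIV libraries, with a median log2 fold change of -0.81 (camera adjusted p = 0.0806; adjusted p = 0.722 with an estimated correlation). CTSS, the protease cathepsin S, stood at -1.36 ± 0.53 and HLA-DRA at -0.87 ± 0.54. CTSS had 24.4 to 50.8 normalized counts in HIV libraries 2, 3 and 4, which had the lowest monocyte markers at a mean log2 CPM of 0.72 to 1.17, and 156 and 123 in HIV libraries 5 and 6, which had the highest at 3.21 and 2.45, but 51.0 in HIV library 1 at 2.39. Of 21 class I genes, 15 were higher, with a median of 0.27 (adjusted p = 0.173), with NLRC5, the class I transactivator, at 1.04 ± 0.39 and HLA-E at 0.43 ± 0.20. Of 47 type I interferon response genes, 35 were higher and 12 lower, with a median of 0.29 (adjusted p = 0.178). PLSCR1 stood at 0.63 ± 0.29 and LY6E at 1.32 ± 0.61, while HERC6 stood at -1.11 ± 0.49 and MX2 at -1.70 ± 0.94. Over the alternatives LY6E ran from 0.81 to 1.604, HERC6 from -1.49 to -0.54 and MX2 from -2.13 to -0.85. HIV entry and restriction factors had a median of -0.12 over 25 members (adjusted p = 0.606), with CXCR4, a coreceptor of the virus, at 1.29 ± 0.47. The levels of CXCR4 were low, at 11.4 ± 5.75 normalized counts in healthy and 28.7 ± 10.9 in HIV libraries (SD, n = 3 and 6). Innate sensing and inflammasome genes had a median of -0.18 over 20 members (0.616), and NF-kB targets and cytokines of -0.13 over 11 (0.717).

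General cell processes showed small medians. The 70 cytosolic ribosomal protein genes had a median of -0.12, with 46 lower and 24 higher (camera adjusted p = 0.233), and 22 of the 71 such genes in both deposited tables had values over 4-fold higher in the smaller table. Nuclear oxidative phosphorylation genes had a median of -0.02 over 66 members (adjusted p = 0.627), with NDUFS6, a complex I subunit, at -0.98 ± 0.37. Splicing machinery had a median of -0.07 over 43 members (0.265), the proteasome of 0.08 over 29 (0.676), glycolysis of 0.04 over 19 (0.856) and heat shock and unfolded protein response of 0.10 over 25 (0.606). Oxidative stress genes had a median of 0.05 over 27 members (0.895), with GPX1, a glutathione peroxidase, at 0.62 ± 0.23. Apoptosis regulators had a median of 0.13 over 25 members (0.353), immediate early genes of 0.08 over 12 (0.628), histone transcripts of -0.13 over 37 (0.233), cholesterol and lipid handling of 0.07 over 15 (0.233) and drug metabolism and nucleoside handling of -0.11 over 19 (0.956).

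With camera at the preset correlation, 0 of 34 lists passed, as did 0 with an estimated correlation and 0 with fry's directional test. In fry's test for change in either direction 1 list passed, the ABC transporters, which hold ABCC4. Median, mean and direction of the test differed in sign for erythroid, secretion, eicosanoid, oxidative stress and ABC transporter genes. The count of lists rested on single libraries: without HIV library 5, 4 lists passed, with class II, ribosomal protein and monocyte genes lower and interferon genes higher. It was 3 without healthy library 3, 3 without HIV library 4, 2 without HIV library 1, 1 without HIV library 6 and 5 without HIV libraries 1 and 5, and with an estimated correlation these lists had adjusted p-values of 0.511 to 0.722 in the same fits.

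**Figure D2:**
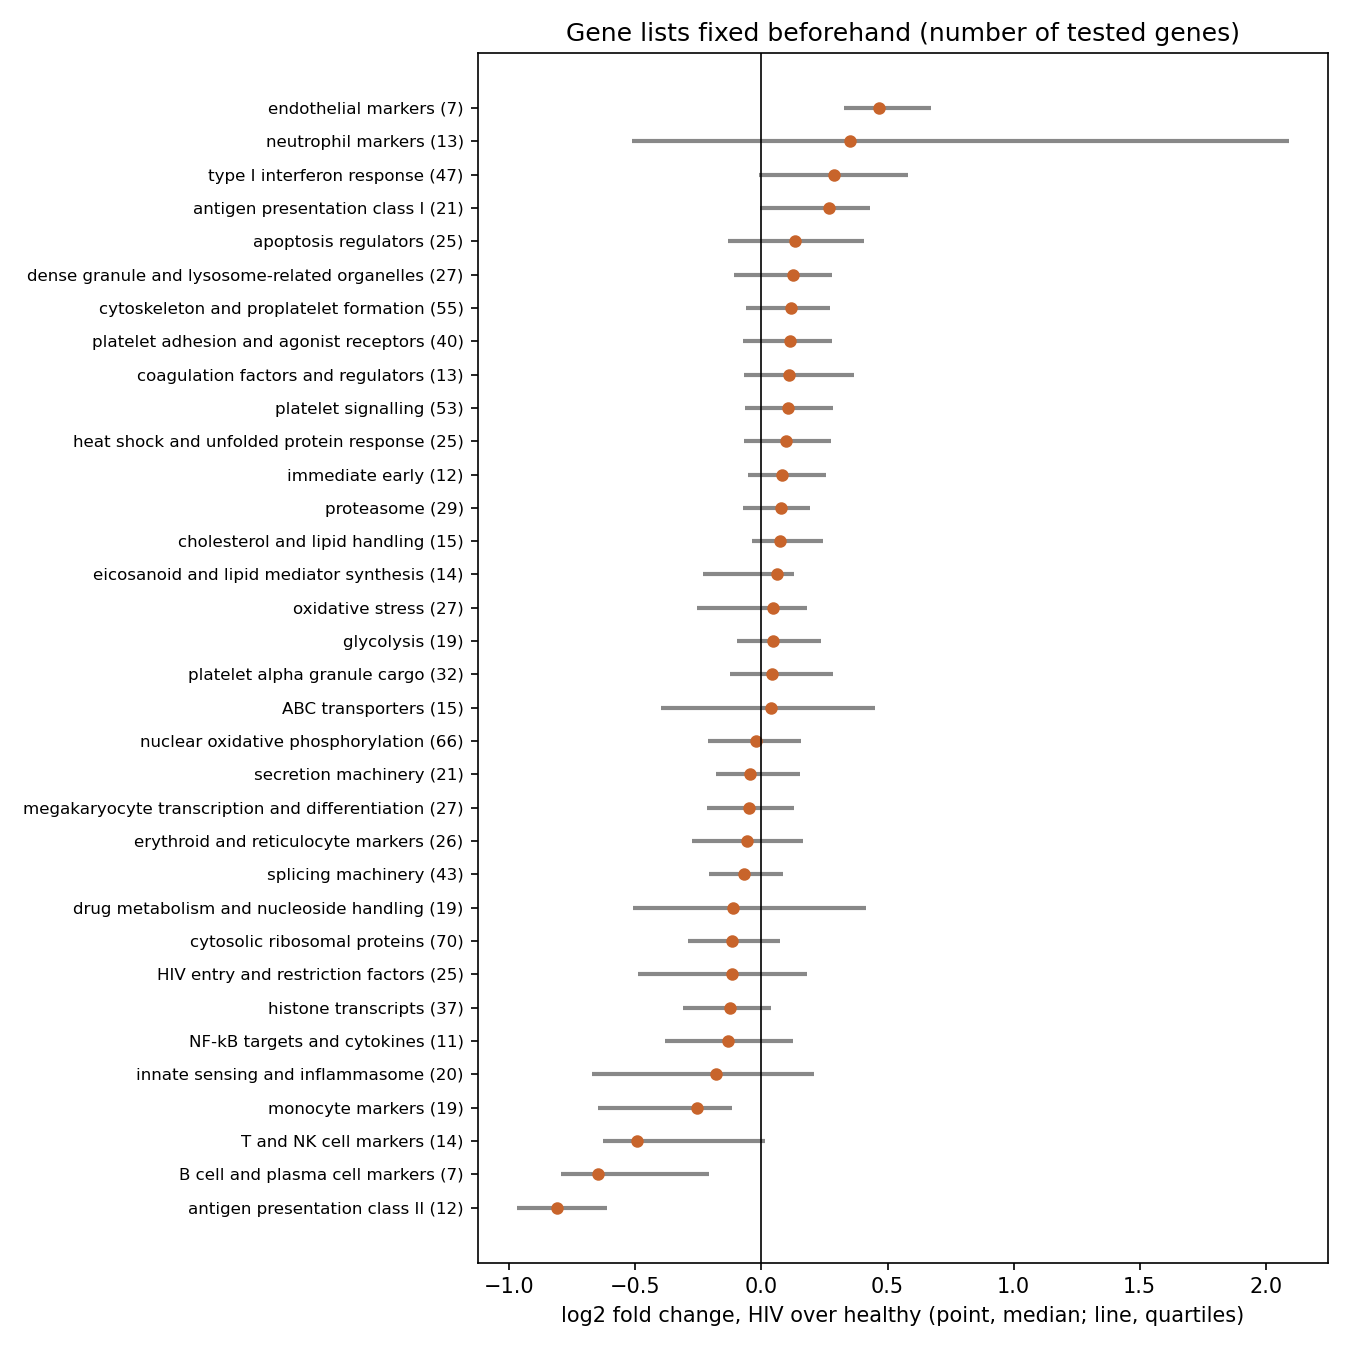
Median log2 fold change of HIV over healthy libraries (points) and quartiles (lines) of the tested members of 34 gene lists, with the number of tested members in brackets. Class II antigen presentation has the lowest median at -0.81, endothelial markers have the highest at 0.47, and 0 of the 34 lists passed the camera test.

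Transcripts of other blood cells were present in both groups, and no difference passed the exact permutation test, whose smallest possible p of 0.0119 does not let a single measure of 8 pass after adjustment. Neutrophil markers had a mean log2 CPM of 0.29 ± 0.37 in healthy and 1.01 ± 1.44 in HIV libraries (SD, n = 3 and 6; exact p = 0.524), with HIV library 5 at 3.55 and HIV library 1 at 1.74. Monocyte markers stood at 2.01 ± 0.37 and 1.84 ± 0.98 (exact p = 0.774), with HIV library 5 at 3.21. T and NK cell markers stood at 0.11 ± 0.25 and -0.14 ± 0.36 (exact p = 0.321), B and plasma cell markers at 0.16 ± 0.21 and 0.10 ± 0.56 (exact p = 0.905), erythroid markers at 2.94 ± 0.22 and 2.96 ± 0.42 (exact p = 0.952) and endothelial markers at -0.16 ± 0.06 and 0.01 ± 0.16 (exact p = 0.131). Haemoglobin genes held 0.0305% ± 0.00881 of reads in healthy and 0.0284% ± 0.0267 in HIV libraries (exact p = 0.929), with HIV library 1 at 0.0771%. Over these 8 measures, counting the share of the 10 highest genes (exact p = 0.560), the adjusted exact p was 0.952 for each.

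As gene lists, these markers did not pass either. T and NK cell markers had a median log2 fold change of -0.49 over 14 tested genes and B and plasma cell markers of -0.65 over 7 (camera adjusted p = 0.233 for both), while monocyte markers had -0.25 over 19 and neutrophil markers 0.35 over 13 (0.353 for both). Within the neutrophil markers, MMP8 and DEFA4, granule proteins, stood at 3.30 ± 1.39 and 3.08 ± 1.53 and LCN2, lipocalin 2, at -0.71 ± 0.31. Without HIV library 5, MMP8 stood at 2.55 and DEFA4 at 2.17, and over the alternatives MMP8 ran from 2.07 to 4.80 and DEFA4 from 1.505 to 4.88. Endothelial markers had a median of 0.47 over 7 genes (0.353), and erythroid markers of -0.06 over 26 (0.616), with HBB at -1.10 ± 0.46.

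**Figure D3:**
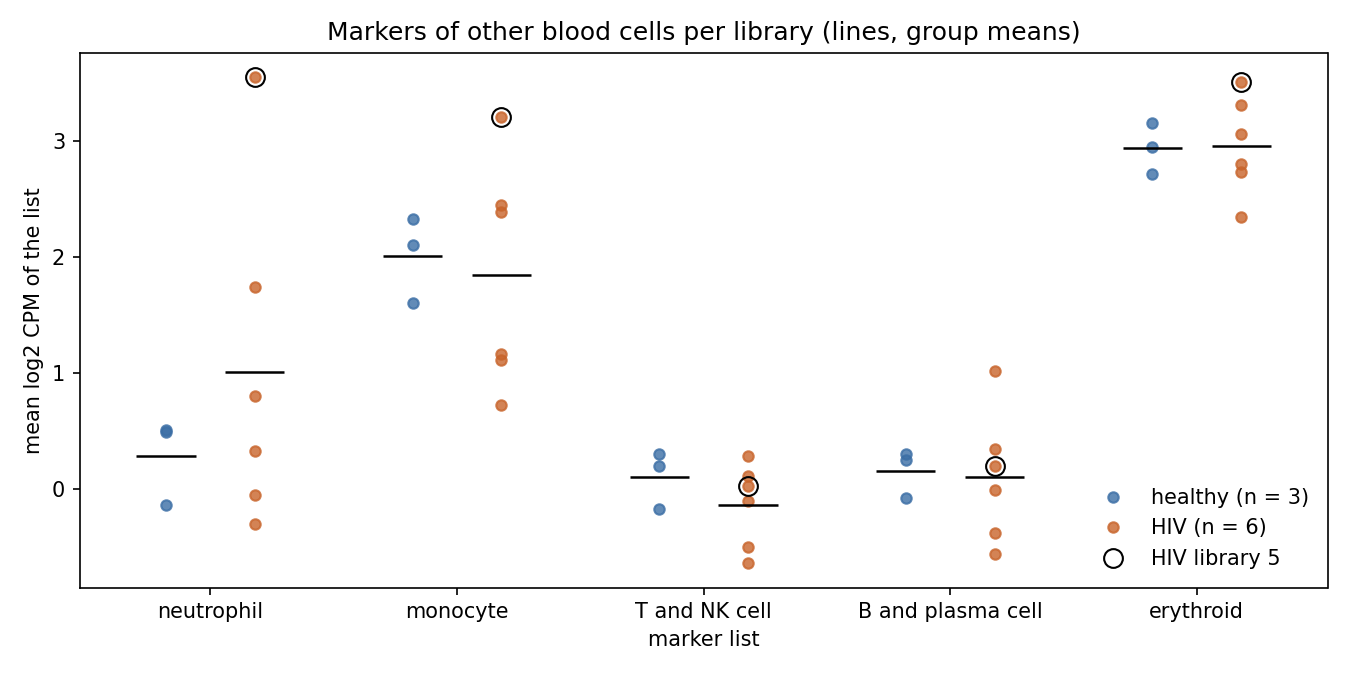
Mean log2 CPM of marker lists of other blood cells in 3 healthy and 6 HIV libraries; points are libraries, short lines are group means, and open rings mark HIV library 5. HIV library 5 is at 3.55 for neutrophil and 3.21 for monocyte markers, above the other libraries, and lies within the range of the other HIV libraries for T and NK cell and B cell markers.

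Depth and gene detection overlapped between the groups. Healthy libraries had 5723600 ± 662981 reads (SD, n = 3) and HIV libraries 6374662 ± 957931 reads (SD, n = 6; exact permutation p = 0.310). Genes with at least 1 read numbered 10782 ± 214 in healthy and 11336 ± 801 in HIV libraries (exact p = 0.310), and genes with at least 10 reads numbered 5753 ± 381 and 5999 ± 383 (exact p = 0.393). The adjusted exact p was 0.393 for each of these 3 measures. HIV library 1 had the most detected genes, 12555, at the lowest depth. At that depth in each library, 10529 ± 34.7 genes were expected in healthy and 10911 ± 1029 in HIV libraries (exact p = 0.667). The leading principal component held 22.4% of the variance and ran from HIV library 4 to HIV library 5, with the healthy libraries between them.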

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

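The criterion for a library far from the others of its group was fixed beforehand: within the 6 HIV libraries, the gap of the highest or lowest library to its nearest neighbour, as a share of the whole range, had to exceed 0.625. The 3 healthy libraries were too few for it. It was applied to 12 library measures, of which 0 exceeded it, and to the log2 values of 145 named genes, of which 8 did. Chance gives about 5% of groups such a gap, so this number of genes is about what chance gives, and no explanation was weighed for them.

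The shares of the range were 0.769 for H2AFZ, high in HIV library 4, 0.758 for DYNLL1, low in HIV library 5, and 0.728 for EBF1, low in HIV library 3. They were 0.708 for NLRC5, high in HIV library 2, and 0.696 for CD14, high in HIV library 1. ADRA2A at 0.674 and HPS1 at 0.664 were low in HIV library 4, and SLC7A11 at 0.665 was low in HIV library 6.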

How the results depend on the processing

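TMM factors in limma and for the lists, edgeR with TMM, DESeq2 on doubled reads, limma without robust moderation, pseudocounts of 0.5 and 8 and leaving out HIV libraries 1 and 5 were chosen after seeing the data. ABCC4 was higher in HIV libraries in all 30 alternatives, with a log2 fold change of 1.82 to 2.24 and an adjusted p of 2.00e-07 to 0.394, and it passed the threshold in 9 of them. These were DESeq2 on recovered reads (2.08, adjusted p = 3.74e-05) and on doubled reads (2.08), limma-voom (2.05, adjusted p = 0.0395), library totals (2.05), no filter on low genes (2.04), a leukocyte (2.06) or erythroid (2.06) score as covariate, 1 surrogate variable (2.17), and adjustment over its list alone (2.04, by testing fewer genes). Without a filter the values of ABCC4 were the same, and its unadjusted p changed only through the moderation of variances over more genes. The adjusted p of 2.00e-07 is therefore not stronger evidence from ABCC4 itself. For the remaining alternatives the cause was not tested. The median standard error was 0.43 on the log2 scale at 4840789 to 7687306 reads per library, where libraries of a group already differed beyond counting noise.

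The count of genes past the threshold stayed 0 in 20 of 30 alternatives. It was 1, ABCC4, with library totals, DESeq2 on recovered reads and on doubled reads, limma-voom, each of the 3 covariate fits and an adjusted p under 0.1, and 3 (ABCC4, CPXM2 and MESTIT1) with no filter. When each library was left out in turn it ran from 0 to 1, and the 1 gene, without healthy library 1, was CD36; the cause was not tested. The count of lists stayed 0 with an estimated correlation, fry's directional test, TMM and the stricter filter. It was 5 without HIV libraries 1 and 5, and ran from 0 to 4 when each library was left out in turn. Counts for the marker measures and for depth were 0 in the alternatives run. With so few libraries a single marker measure could not pass after adjustment, nor could a single depth measure with a library left out. Those counts therefore say nothing about stability. The test of genes detected after thinning to the smallest total could pass and did not (exact permutation p = 0.667). The planned DESeq2 size factors for the lists are the scaling of the deposited values, so TMM took their place.

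The 144 other named genes gave 3935 pairs of gene and alternative, of which 3916 kept direction and side of the threshold. CD36 without healthy library 1 and CPXM2 without a filter newly passed, and 17 pairs changed sign in genes that did not pass. Without HIV libraries 1 and 5, B2M was at 0.022 and SPARC at 0.017; with 1 surrogate variable B2M was at 0.042. TCL1A was at 0.097 with edgeR and TMM, 0.085 with edgeR and DESeq2 size factors, 0.097 with edgeR without robust dispersion, 0.057 with DESeq2 and 0.052 with DESeq2 on doubled reads. In the smaller table RPS28 was at 0.033 and SLC25A37 at -0.43. Pairs whose gene was not in the fit have no value. With each library left out in turn, B2M ran from -0.26 to 0.069 (above 0 without healthy library 1 or HIV library 5), GZMB from -1.32 to 0.20 (above 0 without healthy library 1), PPBP from -0.052 to 0.395 and ESM1 from -0.057 to 1.13 (below 0 without healthy library 2), and MCL1 from -0.025 to 1.03 and BIRC3 from -0.074 to 1.23 (below 0 without healthy library 3). The cause was not tested.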

Other observations

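The tests of explanations for ABCC4, apart from the splits of the libraries, and those for neutrophil transcripts were chosen after the result was seen, although the ABCC4 fits other than TMM had been planned as alternatives. HIV library 5 carried transcripts of neutrophil granules, proteins made in the marrow by neutrophil precursors. Of 12 such genes measured, 11 were above each of the other 5 HIV libraries. LTF, lactoferrin, had 1962 normalized counts in HIV library 5 against a median of 67.5 in the other 5 HIV libraries, CAMP, the cathelicidin precursor, 1033 against 19.3, DEFA4, a defensin, 917 against 11.5, and MPO, myeloperoxidase, 549 against 9.88. HIV library 1 was second among the HIV libraries for each of the 11 raised genes, so the pattern was not confined to HIV library 5. In HIV library 1, MPO was at 228, LTF at 396, BPI at 165 and ELANE at 80.1. The healthy means were 41.4 ± 49.5 for LTF and 7.04 ± 4.72 for MPO (SD, n = 3). LCN2 was the exception, at 3038 against a median of 4497, and was abundant in healthy libraries as well, at 7751 ± 2644. These genes were chosen after their values were seen.

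Residual neutrophils or their precursors may be the source of this pattern in HIV library 5, although negative selection is meant to remove them. By the criterion fixed beforehand, HIV library 5 was not flagged for neutrophil markers, MMP8 or DEFA4. A lower share of platelet RNA would raise the markers of every other blood cell, but T and NK cell markers stood only 0.20 log2 units above the mean of the other 5 HIV libraries, within their SD of 0.39, and B and plasma cell markers 0.11 above (SD 0.63), while neutrophil markers stood 3.05 above (SD 0.81), monocyte markers 1.64 (SD 0.80) and erythroid markers 0.66 (SD 0.36), so the markers of other cells did not rise alike. Of 14 transcripts of mature neutrophils, 12 were above each of the other 5 HIV libraries. The median difference over the 14 was 2.13 log2 units, and its size is uncertain because most levels were low. Among the 12, CYP4F3 and VNN3 had only 2 reads each in HIV library 5, and FCGR3B was at 98.8 against a highest other value of 88.9. PROK2, at 106 against a highest other value of 217, and MGAM, at 5.20 against 7.74, were not above the others. CXCR2 was at 543 against 160, and S100A8, an abundant myeloid transcript outside these 14, at 8121 against a highest other value of 2396. Granule transcripts of precursors stood a further 2.38 log2 units above the mature ones. The median level in the other 5 HIV libraries was 7.84 normalized counts for the former and 4.68 for the latter, too near the floor to compare folds. Mature neutrophils and their precursors therefore cannot be told apart as sources, and no biological explanation was tested. PTPRC, a gene of all leukocytes, was at 206 against a highest value of 208 in the other 5 HIV libraries. That gene alone gives no support to residual neutrophils or their precursors as the source, which stays open.

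ABCC4 was higher in HIV libraries by 2.04 ± 0.31 log2 units, and 4 technical explanations were weighed. The scaling between libraries does not account for it, since the lowest value over 4 scalings was 2.01 ± 0.34. Residual leukocytes and residual red cells are argued against by covariate fits, in which ABCC4 stood at 2.06 ± 0.30 and 2.06 ± 0.27 and passed the threshold, and the counting behind the larger table by the smaller table, which gave 2.001 ± 0.31. Chance was not excluded in a search over all genes: in 14 of the 84 splits of the libraries, the real split included, some gene had a limma p as small as that of ABCC4, 1.04e-05, and the smallest p in another split was 5.32e-09. HIV, its treatment and any other difference between these donors stay open as untested explanations, since the design gives no group that separates them. Any difference in collection, preparation or sequencing that coincided with group stays open as well. The labels give no batch, and none of the fits above could separate it from group.

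Of the 84 splits, 63 gave at least as many genes at an unadjusted p under 0.05 as the real 253, with a highest count of 1015 in another split, so chance was not excluded for that count, and splits with several times the real count point to a structure of the samples. For genes and for lists past the threshold the real count was 0 in limma and in camera, which all 84 splits reach by definition, so those comparisons decide nothing; the highest count in another split was 12 for genes and 12 for lists. At least 1 list passed camera with the preset correlation in 78 of 84 splits, which points to structure shared by groups of genes across these libraries, and the lists that passed when single libraries were left out did not pass with an estimated correlation.

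The deposited tables differ strongly for some genes: 164 of 4703 shared genes had values over 4-fold higher in the smaller table and 1 was over 4-fold lower. Among them were nuclear copies of the mitochondrial ribosomal RNA gene, with MTRNR2L2 at a median of 281 normalized counts in the larger and 580142 in the smaller table, and RPL41, a ribosomal protein gene, stood at 144 and 7116. Overlapping genes were not more frequent among the higher genes. Exons of 45.7% of the 140 higher genes found in the annotation overlapped another gene, against 49.6% of the other shared genes found there (Fisher's exact p = 0.391). Overlaps were counted on either strand in an annotation of another build, so this cannot show how they acted in the authors' counting. Near-identical copies may contribute, since 45.0% of the 140 higher genes found in the annotation had an annotated pseudogene copy against 16.3% of the others (Fisher's exact p = 5.93e-15). Copies were counted by pseudogene name only. MTRNR2L2, itself one of the nuclear copies above, was therefore counted as having none, which is no evidence against this explanation. How the authors treated reads that match several places is not given in the sources used here. Of the higher genes, 92 were among the genes tested.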
